A study of Mus musculus with 4 samples.

How the data were processed

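Whole-embryo single-cell RNA was measured in 4 libraries, labelled EDG7.5, EDG9.5, Reactivated and E5.5, each from embryos pooled before dissociation with TrypLE and captured on the BD Rhapsody system. Each file lists genes, cell barcodes and counts. The deposited counts are whole numbers per gene and barcode, made by the authors, per the submitters' processing notes, with UMI-tools 1.0.1, STAR 2.7.1a, Subread and featureCounts 1.6.4 on mm10. They were read as UMI counts because UMI-tools is named and the layout is that of its count table. The gene annotation, the strand setting and the rule that chose the barcodes are not given in the sources used here. The files hold 25437 gene names, of which 23827 match a symbol of the GRCm38.p6 gene table; 5 list genes were matched through an older name, such as Ctgf for Ccn2 and Sc4mol for Msmo1.

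Cells with at least 1000 UMIs, at least 500 genes and under 25% of UMIs from mitochondrially encoded genes were kept: 1670 in EDG7.5, 2458 in EDG9.5, 673 in Reactivated and 9541 in E5.5. Doublets called by Scrublet, as in scanpy 1.11.5 with its automatic threshold, were then removed, 12, 7, 2 and 283 cells in the same order. Each library was clustered on its own, since stage and library are the same thing with 1 library per stage. The steps were log CPM, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. A cluster was named epiblast, endoderm or trophoblast from fixed marker lists when its best list led by at least 0.5 log2 and at least 3 of its markers reached 20 CPM. Lists for decidual stroma, uterine epithelium, immune, erythroid and endothelium cells were scored the same way, and no cluster took one of these names. The clusters and names are rebuilt here and are not the authors' own. Epiblast, endoderm and trophoblast held 489, 581 and 588 cells in EDG7.5, 582, 863 and 950 in EDG9.5, 205, 303 and 163 in Reactivated and 2639, 2987 and 3632 in E5.5.

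UMIs were summed over the cells of a lineage in a library and given as CPM, a share of UMIs rather than an amount per cell. CPM have exact Poisson intervals, lineage shares exact Clopper-Pearson intervals, and ratios of 2 libraries exact conditional binomial intervals, all at 95% and all covering counting error only. No test was made, as cells are not replicates. Log2 ratios add 10 CPM to both sides. A ratio against 0 UMIs is given as a lower bound with 3 counts over the class in place of 0, a one-sided 95% limit, so the two-sided interval of such a ratio starts lower. The comparisons were EDG9.5 over EDG7.5, Reactivated over EDG9.5 and E5.5 over EDG9.5, with E5.5 over Reactivated for lists alone. For each of 25 gene lists the median log2 ratio was taken over members with at least 10 UMIs in the 2 sums, with a 95% order-statistic interval over members and a percentile among 10000 random lists of the same size drawn within 20 expression bins. Members at 0 in 1 library enter 41 medians; with these members at their bound no median moved by more than 0.28, and 1 changed sign.

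Genes are named by a fixed rule. In each comparison and lineage, these are the 4 genes with the highest and the 4 with the lowest log2 ratio among genes with at least 50 UMIs in the 2 sums and at least 100 CPM in 1 of them, leaving out ribosomal protein, mitochondrially encoded, predicted and haemoglobin genes. The rule gave 72 entries and 61 distinct genes. Members with the highest mean CPM in a list are also named. Some genes are on more than 1 list. Klf4 is on the naive pluripotency and the immediate early lists, and Egr1 on the ERK feedback and the immediate early lists. Ccnd1 is on the WNT target and the ERK feedback lists, and Btg2 on the immediate early and the cell cycle inhibitor lists. Genes in the closing section that neither part of the rule picks were chosen after their values were seen. Cell filters, markers, lists, comparisons, this rule and all alternatives but 1 were fixed before the data were examined. The alternatives were other UMI minimums (2000, or 500 with 250 genes), a mitochondrial limit of 10%, no doublet removal, joint clustering, Leiden resolutions 0.5 and 2, TMM factors from edgeR 4.0.16, totals without ribosomal protein and mitochondrially encoded genes, cells thinned to 1000 UMIs, means over cells, other added CPM, and other member minimums. The trophoblast class without 3 clusters, whose 10 top genes held more genes of another list than of their own, was added after the values were seen.

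The steps were tested on simulated data, with 12 simulated pairs of sums of 8456 to 11946 genes, 200 of them set to differ 2-fold. The ratio intervals held the true ratio for 95.6 to 96.3% of genes. The counts were drawn as independent Poisson counts, as the intervals assume, so this checks the code and not the spread between cells. The median log2 ratio of the 2-fold genes was 0.69 to 0.87, since the added 10 CPM pulls ratios towards 0. Lists drawn at random from the simulated genes, changed ones included, fell in the outer 5% of random lists in 2.5 to 6.5% of cases. Both kinds of list were drawn at random from the same genes, so a rate near 5% was set in advance. The work used Python 3.11.15, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, scikit-image 0.26.0, matplotlib 3.10.9 and R 4.3.3.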

Results

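Single-cell RNA libraries were made from whole wild-type mouse embryos of the strain B6C3F1/J on the BD Rhapsody microwell system, with 1 library per stage label. The labels are EDG7.5, EDG9.5, Reactivated and E5.5, and the series title names embryonic diapause and peri-implantation development. Between 200 and 250 flushed blastocysts went into each of the first 3 libraries, and 50 embryos removed from their implantation sites into the E5.5 library; the label of the Reactivated library adds 30 h of E2 to EDG9.5. The series text also names E4.5, which is not analysed here. The total was 9620232 molecule counts (UMIs) over 1726 barcodes in EDG7.5, 10994918 over 2566 in EDG9.5, 9270833 over 677 in Reactivated and 87507141 over 9560 in E5.5. The median per barcode was 5018.5, 3724.5, 13154 and 8800.5 UMIs in the same order. With 1 library per stage no difference below has a replicate check, and the intervals of CPM, shares and ratios are 95% intervals covering counting error only. Intervals of list medians run over the genes of a list, which are not replicates.

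The first question is which lineages each library holds. Cells fell into epiblast, endoderm (the primitive endoderm and the visceral and parietal endoderm that come from it) and trophoblast, named from fixed marker genes. Of the named cells, trophoblast made up 35.5% (33.2 to 37.8) in EDG7.5, 39.7% (37.7 to 41.7) in EDG9.5, 24.3% (21.1 to 27.7) in Reactivated and 39.2% (38.2 to 40.2) in E5.5, with exact Clopper-Pearson intervals. Endoderm made up 35.0% (32.7 to 37.4), 36.0% (34.1 to 38.0), 45.2% (41.3 to 49.0) and 32.3% (31.3 to 33.2). Epiblast made up 29.5% (27.3 to 31.8), 24.3% (22.6 to 26.1), 30.6% (27.1 to 34.2) and 28.5% (27.6 to 29.4). With cells under 10% mitochondrial UMIs alone the EDG7.5 epiblast share was 42.3%. In EDG9.5 a cluster of 56 cells had endoderm and epiblast markers at like levels and was left unnamed.

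**Figure D1:**
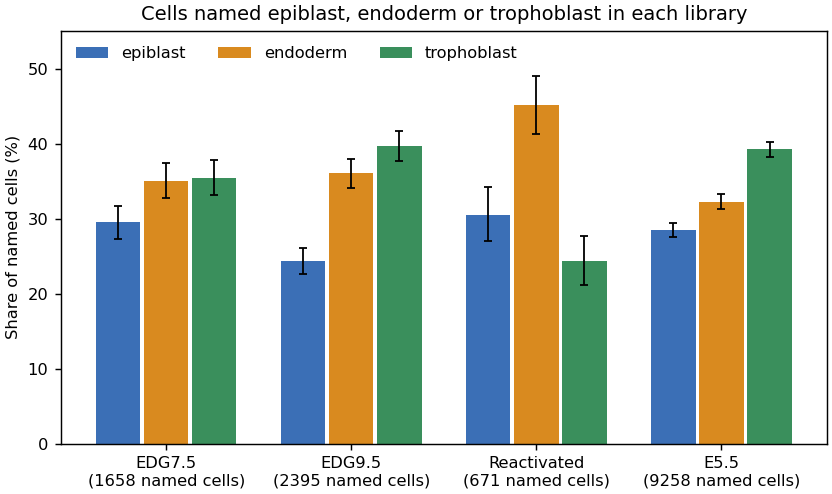
Share of named cells (%) that are epiblast, endoderm or trophoblast in each library, as bars with exact 95% Clopper-Pearson intervals that cover counting error only. The trophoblast bar is lowest in Reactivated, at 24.3%.

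Some clusters were led by genes outside their own marker list. Msx1, on the uterine epithelium list, was among the top genes beside H19 in EDG7.5 clusters 5 (148 cells) and 8 (112 cells) and EDG9.5 clusters 3 (133 cells) and 8 (230 cells), and beside Adh1 in Reactivated cluster 2 (41 cells), while Cdh5 and Pecam1, on the endothelium list, were among the top genes beside the placental lactogens Prl3d1 and Prl3d2 in E5.5 cluster 12 (444 cells). Cdh5 was also among the top genes of E5.5 cluster 3 (637 cells), and Cd52, on the immune list, of Reactivated cluster 0 (52 cells). All these clusters had trophoblast as their highest list and were kept there. In 3 of them (EDG7.5 cluster 8, EDG9.5 cluster 3 and E5.5 cluster 12) the 10 top genes held more genes of another list than of their own, and values without these 3 are given where they differ by more than 1.5-fold. In endoderm, Col3a1, on the decidual stroma list, was among the top genes of Reactivated cluster 3 (115 cells), and Fgf5, on the epiblast list, of cluster 8 (62 cells). The antigen presentation genes Cd74, H2-Ab1 and H2-Aa led EDG7.5 cluster 0, an endoderm cluster, but 49 of the 50 Cd74 UMIs of that library came from 1 cell. Lists of other cell types gave low sums: uterine epithelium at most 318 CPM (299 to 337) in EDG7.5 trophoblast, from Msx1, and decidual stroma at most 109.5 CPM (100.2 to 119) in Reactivated endoderm. The immune list reached 234 CPM (216 to 252) in EDG7.5 epiblast, mostly from Laptm5, and the erythroid list at most 1.56 CPM. The endothelium list reached 252 CPM (234 to 272) in EDG7.5 epiblast, mostly from Pecam1. The lists that named the lineages summed in EDG9.5 to 12001 CPM (11866 to 12137) for epiblast, 18085 CPM (17948 to 18224) for endoderm and 16117 CPM (15999.6 to 16234) for trophoblast in their own lineage.

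The second question is how the Reactivated embryos differed from EDG9.5 embryos. In all 3 lineages, genes of cell division, glycolysis and nuclear-encoded respiration were higher in Reactivated. Lysosome genes were lower in epiblast and trophoblast, and naive pluripotency genes were lower in epiblast. Among genes with large ratios were the methyltransferase Dnmt3b in epiblast, the retinoic acid-degrading enzyme Cyp26a1 in endoderm and the serine synthesis gene Psat1 in trophoblast. Values below are CPM, a gene's share of the summed UMIs of a lineage, given for EDG9.5 and then for Reactivated.

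In epiblast, Ldha, which makes lactate from pyruvate, had 10.3 and 1252 CPM, a ratio of 121 (82.5 to 186). Its partners in glycolysis were higher too, with 908 and 2959 CPM for Aldoa and 291 and 2182 CPM for Pkm, and the list had a median log2 ratio of 1.69 (0.53 to 2.72). Dnmt3b, a de novo DNA methyltransferase, had 96.2 and 1436 CPM, and Lef1, a transcription factor of WNT signalling, 8.35 and 256 CPM. Myrf, a membrane-bound transcription factor, had 1.59 and 164 CPM. Among genes that were lower, Gpnmb, a lysosomal and membrane glycoprotein, had 1014 and 4.68 CPM, 216 (124 to 419) times lower. The glycerol channel Aqp3 had 1205 and 16.8 CPM, the vitamin K-dependent protein Pros1 736 and 17.2 CPM and the calcium sensor S100a1 614 and 30.0 CPM. The naive pluripotency list was lower in 18 of 20 genes, with a median of -1.76 (-2.53 to -0.90). Its sum had 10717 and 3506 CPM in epiblast, 5658 and 1255 in endoderm, and 5039 and 1596 in trophoblast. The list was set for epiblast alone, so sums in the other lineages follow whichever members are abundant there. In EDG9.5 trophoblast, its members Dppa5a and Klf2 had 2123 and 724 CPM. Of the most abundant genes of the naive list in epiblast, Klf4 had 1909 and 146 CPM and Dppa5a 2244 and 1562 CPM. Klf4 is also on the immediate early and dissociation list. The formative and primed list, also set for epiblast alone, was higher in 13 of 18 genes, with a median of 0.81 (-0.13 to 2.74), an interval that reaches 0. Its sum had 2101 and 4288 CPM in epiblast, 648 and 1241 in endoderm, and 694 and 501 in trophoblast. Averaged per cell, Aqp3 had a log2 ratio of -4.71 against -5.50, and S100a1 -3.26 against -3.96; with cells thinned to 1000 UMIs, Klf4 had -2.90 against -3.62.

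In endoderm, the transcription coactivator Cited1 had 22.9 and 837 CPM, a ratio of 36.5 (29.4 to 45.9), and the tight junction gene Cldn6 25.9 and 812 CPM. Cyp26a1, which degrades retinoic acid, had 4.63 and 163 CPM, and Ldha 96.8 and 1239 CPM. The endocytic receptor genes Cubn and Lrp2 had 168 and 1447 CPM and 294 and 1336 CPM, and their list of visceral endoderm transport and lipoprotein genes a median of 2.0 (0.25 to 2.87), or 0.63 over all members of the list in the files. The anterior visceral endoderm list had 1.09 (-0.93 to 2.68), with Lefty1 at 86.2 and 194 CPM and Dkk1 at 163 and 378 CPM, and all members in the files gave 0.46. Averaged per cell, the log2 ratios were larger for Cited1 (5.30 against 4.69), Cldn6 (5.15 against 4.52), Cubn (3.89 against 3.03) and Lefty1 (1.74 against 1.09). Lower genes included the giant scaffold protein Ahnak, with 745 and 23.6 CPM (31.6 (26.1 to 38.6) times lower), Pramel7, a gene of naive pluripotent cells, with 166 and 0.857 CPM, Pros1 with 1032 and 57.0 CPM and Ly6g6e, a surface protein gene, with 145 and 1.29 CPM. Of the parietal endoderm and basement membrane list, 10 of 14 genes were lower, with a median of -0.62 (-1.22 to 0.56), while its most abundant member Sparc had 4115 and 4736 CPM.

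In trophoblast, Psat1 and Slc3a2, of serine synthesis and amino acid uptake, had 15.8 and 888 CPM and 277 and 899.6 CPM. The cathepsin-like gene Ctsll3 had 3 UMIs in EDG9.5 and 1151 CPM in Reactivated, a ratio of 1726 (589.8 to 8375), and 88.9% of its Reactivated UMIs lay in cluster 7, of 33 cells. Its family has close copies, so its count is uncertain. Ldha had 28.9 and 1127 CPM, and Tmem37, a membrane protein gene, 9.78 and 298 CPM. The gap junction gene Gjb2 had 1959.6 and 25.6 CPM, 76.5 (58.1 to 103) times lower. The alcohol dehydrogenase Adh1 had 5569 and 102 CPM, the endocytic adaptor Dab2 2187 and 69.8 CPM and the alkaline phosphatase Alpl 1274 and 39.2 CPM. With cells thinned to 1000 UMIs, the log2 ratio of Gjb2 was -4.82 against -5.79 and that of Adh1 -4.39 against -5.63. The giant cell and ectoplacental list had members both ways, with a median of 1.81 (-2.20 to 3.88) over 7 measured genes. The median was 2.54 with members of at least 50 UMIs alone and 0 over all members in the files. The immune list summed to 3.78 and 78.4 CPM in this lineage, mostly from Cd52. The abundant giant cell list members Gata2 and Ndrg1 were lower, with 746 and 225 CPM and 1266 and 267 CPM. The polar trophectoderm and extraembryonic ectoderm list had 0.74 (-0.17 to 1.54), with Id2 at 1102 and 2292 CPM, and the adhesion and implantation list 0.23 (-0.87 to 1.51), with Lgals3 at 1753 and 1459 CPM and Cldn4 at 1626 and 884 CPM.

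Lists measured in every lineage are given as medians for epiblast, endoderm and trophoblast. Scaling by TMM factors, which assumes that most genes do not differ, moved the median log2 ratio of all measured genes from -0.23 to 0.022 in epiblast and from -0.16 to 0.020 in endoderm, so list medians in these 2 lineages are to be read against those values. G2 and M phase genes had 1.12, 1.30 and 1.84, higher in 27 of 28, 27 of 28 and 28 of 28 genes. The chromosome passenger Birc5 had 37.8 and 557 CPM in trophoblast, a log2 ratio of 3.57, or 4.47 with thinned cells. The ubiquitin-conjugating enzyme gene Ube2c had 108 and 573 CPM in endoderm. S phase genes had 0.86, 0.69 and 1.47, with Rrm2, of nucleotide supply, at 121 and 491 CPM in trophoblast. The G2 and M phase median lay above those of all 10000 random lists of like expression in each lineage, as a description of these libraries. Ribosome biogenesis and MYC targets had 0.80, 0.089 and 1.06, with nucleolin (Ncl) at 1264 and 3055 CPM in epiblast and 1569 and 2379 CPM in endoderm. Glycolysis genes had 1.69, 0.82 and 1.55, though the glucose transporter Slc2a3 was lower in trophoblast, with 1508 and 511 CPM. Nuclear genes of oxidative phosphorylation had 0.55, 0.83 and 0.60, with Atp5g3 at 693 and 1979 CPM in endoderm. Cholesterol synthesis genes had 0.88, 1.14 and 0.42, with Sc4mol at 152 and 635 CPM in endoderm, and polyamine genes 0.30, 0.25 and 0.19, with Srm at 109 and 473 CPM in epiblast.

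Other lists were lower in Reactivated or mixed. Autophagy and lysosome genes had -1.30, -0.37 and -0.89 (in endoderm -0.032 under TMM scaling), with Lamp1 at 1065 and 221 CPM and Cd63 at 1164 and 345 CPM in epiblast. Cell cycle inhibitors and FOXO targets had -0.71, -0.60 and -0.57, with Cdkn1b at 227 and 92.5 CPM in epiblast and Txnip at 162 and 8.04 CPM in trophoblast; with members of at least 50 UMIs alone the trophoblast median was -1.95. Immediate early and dissociation genes had -0.67, -0.56 and -0.70, with Egr1 at 1469.5 and 159 CPM in endoderm and Jund at 1592 and 405 CPM in trophoblast. ERK feedback targets had -0.32, -0.95 and -0.20, with Spry2 at 555 and 81.5 CPM in endoderm; under TMM scaling the epiblast median became 0.093. Fatty acid oxidation genes had -0.32, -0.22 and -0.38, with Cpt1a at 521 and 34.9 CPM in endoderm, where TMM scaling gave 0.067. Ribosomal proteins had 0.28, -0.22 and -0.030, with the endoderm median at 0.14 under TMM scaling. Mitochondrially encoded genes had 0.26, -0.36 and -0.29, with mt-Co1 at 17896 and 6027 CPM in trophoblast. Amino acid and integrated stress response genes had -0.045, 0.24 and 0.66, with the epiblast median at 0.37 under TMM scaling; Asns had 1042 and 276 CPM and Slc7a3 68.0 and 944 CPM there. WNT targets had 0.54, -0.76 and 0.34, with Ccnd1 at 26.2 and 332 CPM in epiblast and Axin2 at 77.4 and 15.9 CPM in endoderm. The trophoblast WNT median rested on 5 genes and was 0.95 with members of at least 50 UMIs, and its Lgr5 had a log2 ratio of 0.95, or -0.27 with thinned cells. YAP targets had -0.20, -0.99 and 0.041, with Amotl2 at 325 and 141 CPM in endoderm; all members in the files gave -0.36 there. Ctgf had 324 and 152 CPM in epiblast, a log2 ratio of -1.04, or -0.40 with thinned cells.

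**Figure D2:**
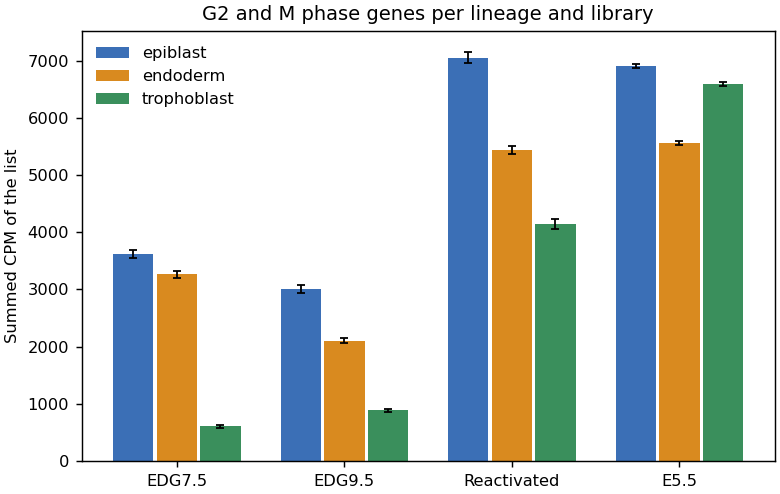
Summed CPM of the 28 G2 and M phase genes per lineage in each library, as bars with exact 95% Poisson intervals that cover counting error only. In each lineage the Reactivated and E5.5 bars are higher than the EDG7.5 and EDG9.5 bars; in trophoblast the EDG9.5 bar is at 888 and the Reactivated bar at 4142 CPM.

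The third question is how E5.5 embryos, taken after implantation, differed from EDG9.5 embryos. Among list medians, those farthest from 0 were the naive pluripotency list, lower in epiblast, and the lipoprotein and transport list, higher in endoderm. Among named genes, Ldha was higher in epiblast, Hand1 was higher in trophoblast, and Adh1 and Gjb2 were lower in trophoblast. Cell division and glycolysis genes were higher in all 3 lineages, as in Reactivated. Values are given for EDG9.5 and then for E5.5. The E5.5 library was collected another way and had more cells, so stage, collection and library cannot be told apart.

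In epiblast, Klf4 had 1909 and 11.6 CPM and Tfcp2l1, also a naive pluripotency transcription factor, 963 and 1.64 CPM, 587 (427 to 832) times lower. The whole naive list was lower in 19 of 20 genes, with a median log2 ratio of -3.67 (-4.83 to -2.98), and Dppa5a had 2244 and 972 CPM. The sum of this list, which was set for epiblast alone, was also lower in the other lineages, with 5658 and 1005 CPM in endoderm and 5039 and 803 in trophoblast. Aqp3 had 1205 and 0.561 CPM and Gpnmb 1014 and 0.864 CPM. Of the formative and primed list, 14 of 20 genes were higher, with a median of 1.61 (-0.18 to 2.95). Its members Dnmt3b and Pim2, a serine/threonine kinase, had 96.2 and 3212 CPM and 23.4 and 884 CPM. Ldha had 10.3 and 1576 CPM, a ratio of 152 (104 to 233), and Gapdh 544 and 2027 CPM. The carbonic anhydrase Car4 had 3 UMIs in EDG9.5 and 406 CPM in E5.5, a ratio of 340.4 (116 to 1651). Nucleophosmin (Npm1), of ribosome biogenesis, had 3123 and 7745 CPM.

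In endoderm, the apolipoprotein Apoc2 had 0 UMIs in EDG9.5 and 1199.5 CPM in E5.5, at least 1466-fold higher when 3 counts over the class stand in for 0, with a counting interval that starts at 1193. Apoa1, of high-density lipoprotein, had 5.18 and 1460.0 CPM and the thyroid hormone carrier Ttr 8.72 and 1229 CPM, a ratio of 141 (99.8 to 206). Their list was higher in 17 of 19 genes, with a median of 3.70 (1.94 to 5.41), and included Spink3 at 66.3 and 3053 CPM and Apoe at 701 and 1992 CPM. The imprinted noncoding RNA H19 had 75.2 and 6232 CPM. Averaged per cell, the log2 ratio of H19 was 7.04 against 6.19 and that of Spink3 6.30 against 5.33. Among lower genes, the nuclear receptor Nr0b1 had 375 CPM in EDG9.5 and 2 UMIs in E5.5, 5075 (1402 to 41949.5) times lower. Ahnak had 745 and 12.8 CPM, the neurofilament gene Nefl 712 and 12.5 CPM and Cpt1a, of fatty acid oxidation, 521 and 10.2 CPM. The anterior visceral endoderm list had 1.68 (-0.30 to 4.17), with Sfrp1 at 82.1 and 279 CPM and Dkk1 at 163 and 112 CPM. The parietal endoderm list had -0.30 (-1.53 to 0.60), or 0.079 under TMM scaling, and its Sparc and Col4a1, at 4115 and 3386 CPM and 2258 and 1998 CPM, also turned higher under TMM scaling.

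In trophoblast, Hand1, a transcription factor of giant cells, had 2.0 and 2239 CPM, a ratio of 1119 (589 to 2447). Phlda2, an imprinted growth regulator, had 2 UMIs in EDG9.5 and 1033 CPM in E5.5, a ratio of 2322 (643 to 19173). The placental lactogens Prl3d1 and Prl3d2 had 0 UMIs in EDG9.5 and 522 and 474 CPM in E5.5, at least 782-fold and at least 709.9-fold higher with the same 3 counts, and counting intervals that start at 636 and 577. They are near-identical copies, so their split is uncertain. Without those 3 clusters, their log2 ratios were 0.84 and 0.96 against 5.73 and 5.60, so they rest on E5.5 cluster 12. The endothelium list summed to 8.0 and 240.3 CPM in trophoblast, mostly from Cdh5, which had 157 CPM in E5.5. The giant cell and ectoplacental list had members both ways, 6 of 9 higher, with a median of 3.09 (-1.63 to 5.73), 1.95 without those clusters and 0.047 over all members in the files. Adh1 had 5569 and 1.33 CPM and Gjb2 1959.6 and 0.331 CPM, 5912 (3302 to 11847) times lower. Dppa1, a gene of early embryos, and BC053393, a gene with close copies, had 1735 and 0.874 CPM and 1788 and 2.68 CPM. The polar trophectoderm and extraembryonic ectoderm list had 1.15 (0.19 to 2.47), with Ddah1 at 666 and 1007 CPM. The adhesion and implantation list had 0.40 (-1.70 to 1.33), while its abundant members Lgals3 and Cldn4 were lower, with 1753 and 138 CPM and 1626 and 146 CPM.

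**Figure D3:**
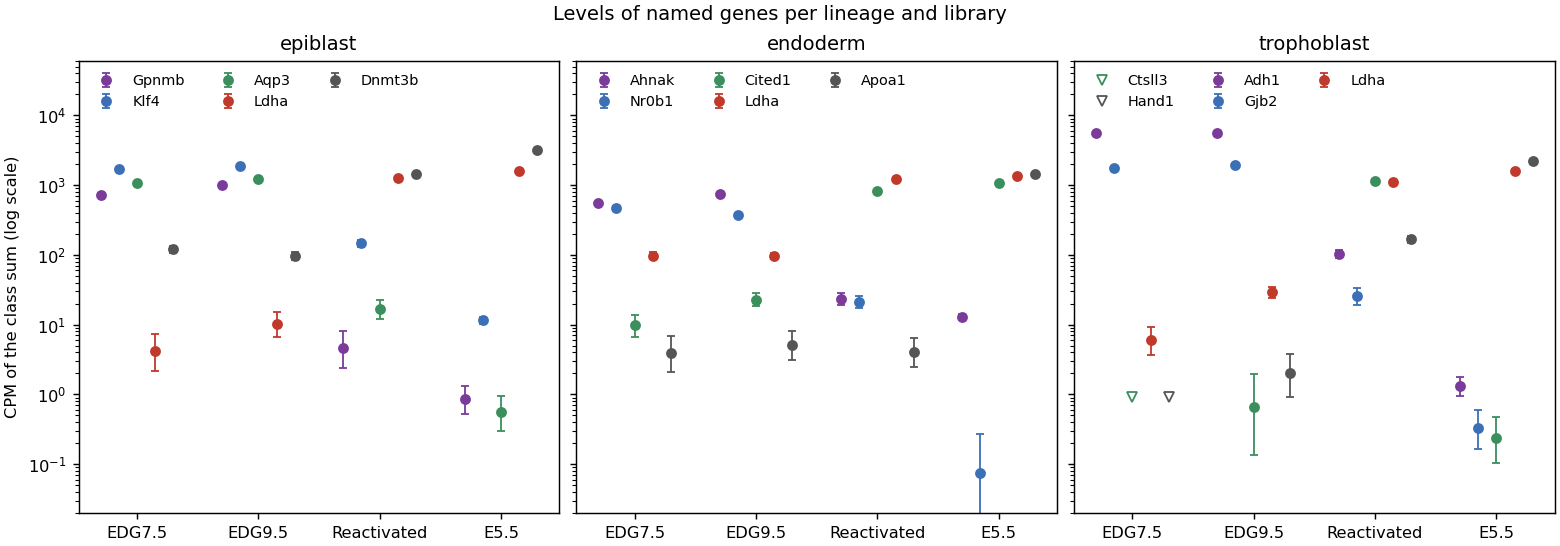
CPM (log scale) of 5 named genes per lineage in each library, with exact 95% Poisson intervals that cover counting error only; open triangles are at 3 counts over the class for genes with 0 UMIs. Gpnmb, Aqp3, Ahnak, Adh1 and Gjb2 are lower, and Ldha, Dnmt3b, Cited1 and Hand1 higher, in Reactivated and E5.5 than in EDG9.5.

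Lists measured in every lineage are again given for epiblast, endoderm and trophoblast. TMM scaling moved the median of all measured genes from -0.032 to 0.077 in epiblast and from -0.056 to 0.056 in endoderm. G2 and M phase genes had 1.01, 1.41 and 2.62 and S phase genes 1.31, 0.89 and 1.91, with Top2a at 186 and 883 CPM in epiblast. Ribosome biogenesis and MYC targets had 0.93, 0.22 and 1.66 and glycolysis genes 0.72, 1.02 and 1.99, with Gapdh at 304 and 2076 CPM in trophoblast and the lactate transporter Slc16a1 at 174 and 1888 CPM in endoderm. Nuclear oxidative phosphorylation genes had 0.39, 0.59 and 0.17 and cholesterol synthesis genes 0.44, 0.39 and 1.18. Autophagy and lysosome genes had -1.27, -0.19 and -0.79, with Psap at 5261 and 416 CPM in trophoblast; TMM scaling gave 0.13 in endoderm. Mitochondrially encoded genes had -0.0057, -0.21 and -0.89, with 0.21 and 0.0066 in epiblast and endoderm under TMM scaling; in trophoblast mt-Co1 had 17896 and 3723 CPM. Ribosomal proteins had 0.24, -0.50 and -0.084, and immediate early genes -1.49, -1.18 and -0.38. Fatty acid oxidation genes had -0.38, -0.053 and -0.58, with 0.24 in endoderm under TMM scaling and Acadl at 496 and 46.7 CPM in trophoblast. Amino acid and integrated stress response genes had -0.16, -0.24 and 0.94, with 0.22 and 0.085 in epiblast and endoderm under TMM scaling and Nupr1 at 802 and 3.13 CPM in trophoblast. Cell cycle inhibitors had -0.71, -0.53 and -0.49 and ERK feedback targets -0.87, -0.71 and 0.59, with Egr1 at 839 and 30.3 CPM and Spry2 at 659 and 82.6 CPM in epiblast. Of these, Egr1 is also on the immediate early list. Polyamine genes had 0.44, 0.078 and 0.29 and WNT targets -0.18, -0.23 and 0.22. YAP targets had -0.32, 0.024 and 0.068, with 0.048 in epiblast under TMM scaling and -0.031 in endoderm without ribosomal protein and mitochondrially encoded genes in the total.

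Between E5.5 and Reactivated, compared by lists alone, the medians farthest from 0 were those of visceral endoderm transport and naive pluripotency. Naive pluripotency genes were lower in E5.5 in 20 of 20 genes, with a median of -1.67 (-2.96 to -1.26), and Klf2 had 482 and 3.02 CPM in Reactivated and E5.5. Visceral endoderm transport genes were higher, with 2.04 (0.50 to 4.03) and Spink3 at 653 and 3053 CPM. The formative and primed list had 0.71 (-0.61 to 0.90), the anterior visceral endoderm list 1.6 (-1.39 to 3.23) and the giant cell list 0.45 (0.041 to 3.67), with Hand1 at 167 and 2239 CPM. G2 and M phase genes had -0.060, 0.14 and 0.80 in epiblast, endoderm and trophoblast, so trophoblast alone had a median interval above 0, at 0.80 (0.43 to 1.12). Oxidative phosphorylation genes were lower in all 3 lineages, at -0.21, -0.19 and -0.42, and cholesterol synthesis genes had -0.37, -0.71 and 0.30, with Sc4mol at 635 and 157 CPM in endoderm. Glycolysis genes had -0.13, 0.0081 and 0.52, and the endoderm value was negative without ribosomal protein and mitochondrially encoded genes in the total. Autophagy and lysosome genes had -0.14, 0.22 and 0.13.

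The last question is whether EDG9.5 embryos differed from EDG7.5 embryos. They were more alike: the genes picked by rule had ratios from 1.67 to 2.45, or for lower genes from 0.393 to 0.585, where the other comparisons reached ratios above 1000. Ribosomal protein genes were higher in all 3 lineages of EDG9.5. Genes of mitosis were lower in endoderm and epiblast and higher in trophoblast. Values are given for EDG7.5 and then for EDG9.5.

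In epiblast, the stress-induced transcription factors Ddit3 and Atf5 had 73.4 and 179.6 CPM and 80.4 and 161 CPM, a ratio of 2.45 (2.07 to 2.90) for Ddit3. The nuclear noncoding RNAs Malat1 and Neat1 had 1275 and 2846 CPM and 52.1 and 109 CPM. Phlda2 had 116 and 52.5 CPM, the melanosome gene Pmel 266 and 141 CPM, the ISG15-conjugating enzyme gene Ube2l6 156 and 87.0 CPM and the histone variant gene H2afv 462 and 269.9 CPM. The naive list had a median of 0.031 (-0.13 to 0.21) and the formative list 0.081 (-0.12 to 0.30). In endoderm, the linker histone gene Hist1h1c had 204 and 462 CPM, Cubn 79.2 and 168 CPM, and the immediate early genes Btg2 and Fos 104 and 219 CPM and 291 and 582 CPM. The digestive protease gene Pgc had 949 and 468 CPM, the mitotic genes Cenpf and Birc5 147 and 70.9 CPM and 188 and 94.6 CPM, and the nucleotidase gene Nt5e 108 and 52.6 CPM. With cells thinned to 1000 UMIs, the log2 ratio of Birc5 was -1.55 against -0.92. The visceral endoderm transport list had 0.45 (0.12 to 0.96), the anterior list -0.071 (-0.13 to 0.99) and the parietal list -0.073 (-0.24 to 0.063). Cubn, Spink3, S100g and Amn, of the visceral list, were among the top genes of EDG9.5 endoderm cluster 9 (108 cells). No EDG7.5 endoderm cluster had them among its top genes. How much of the difference came from that cluster was not measured. In trophoblast, the snoRNA host gene Snhg6 had 258 and 446 CPM, the tight junction gene Cldn23 163 and 279 CPM, Crebrf, a regulator of stress responses, 78.9 and 138 CPM and Fosb 231 and 388 CPM. The mitochondrial adenylate kinase gene Ak4 had 105 and 41.4 CPM, Pigp, of membrane anchor synthesis, 535 and 248 CPM, the dehydrogenase gene Hsd17b6 129.8 and 59.1 CPM and the cathepsin-like gene BC051665 122 and 60.0 CPM.

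Among lists, ribosomal proteins had 0.21, 0.36 and 0.55 in epiblast, endoderm and trophoblast, with Rps28 at 3507 and 5658 CPM in trophoblast. G2 and M phase genes had -0.22 (-0.30 to -0.094), -0.63 (-0.81 to -0.51) and 0.34 (0.22 to 0.51), lower in 28 of 28 genes in endoderm and higher in 28 of 28 in trophoblast. S phase genes had -0.24, -0.18 and 0.043, and the trophoblast value was negative with thinned cells. Oxidative phosphorylation genes had -0.20, -0.085 and -0.056 and mitochondrially encoded genes -0.27, -0.30 and -0.19, with mt-Cytb at 17646 and 13011 CPM in endoderm. Cholesterol synthesis genes had -0.058, -0.0022 and -0.43, with Insig1 at 331 and 207 CPM in trophoblast; the epiblast value was positive with thinned cells and the endoderm value, near 0, under TMM scaling. Immediate early genes had 0.21, 0.23 and 0.14, with Egr1 at 811 and 1469.5 CPM in endoderm. Glycolysis genes had 0.13, 0.097 and 0.23, and the endoderm value was negative with thinned cells.

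**Figure D4:**
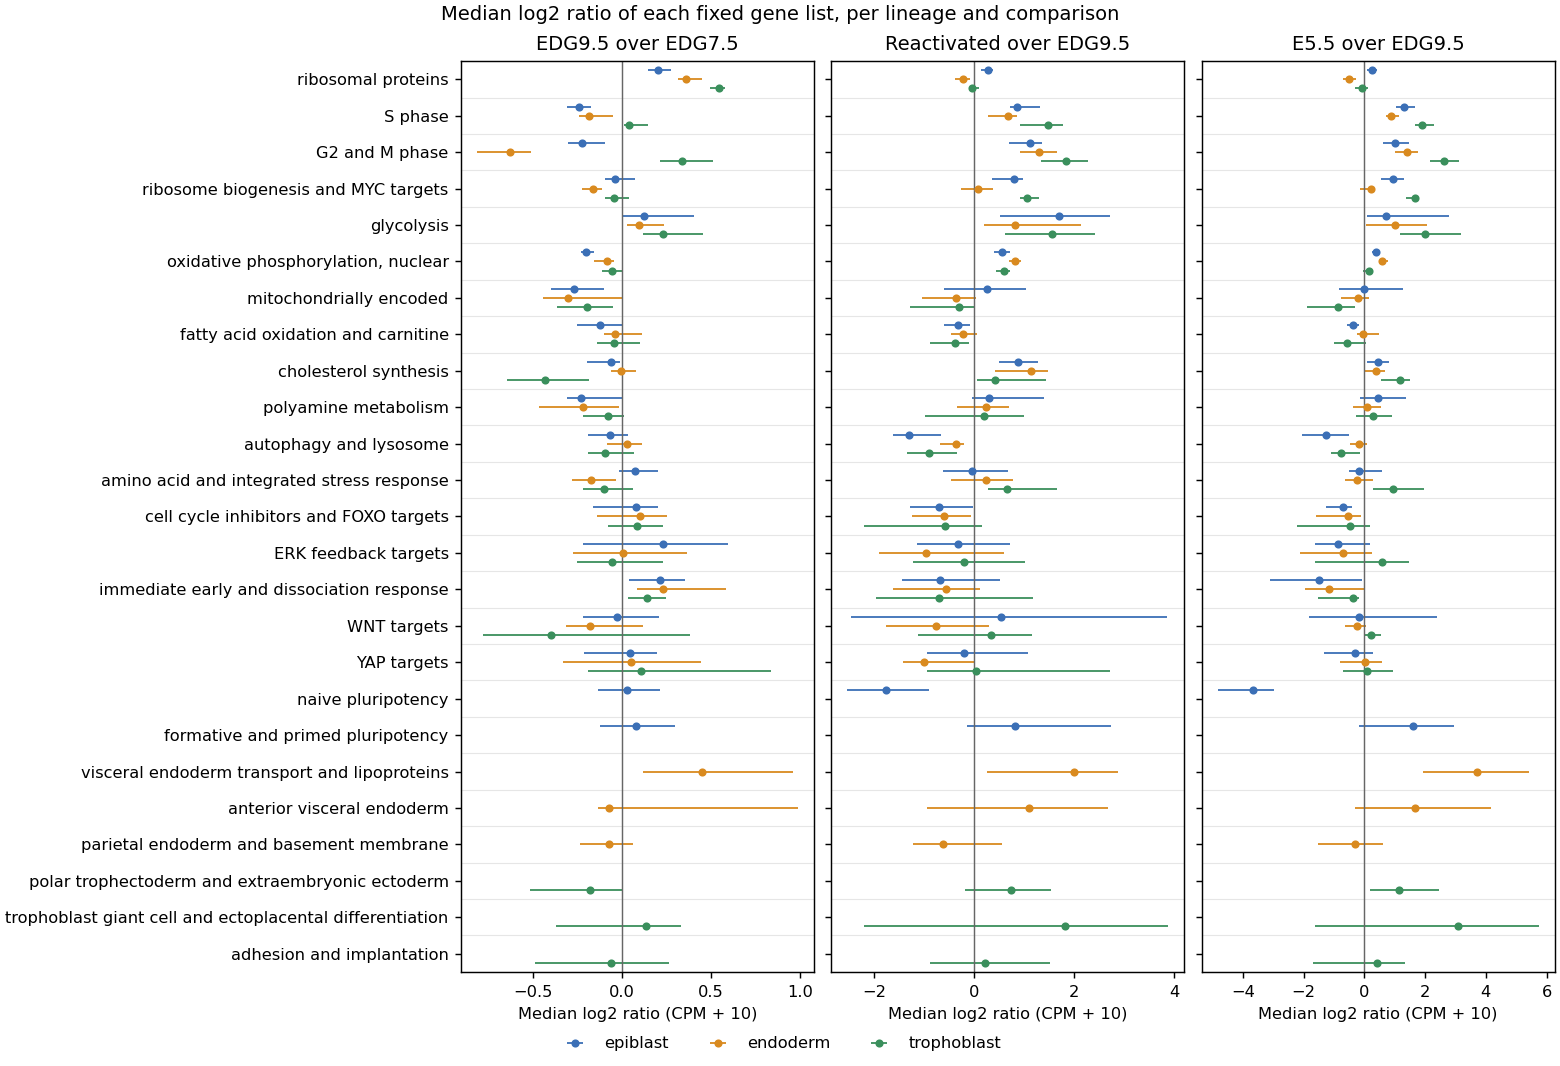
Median log2 ratio (CPM plus 10) of each fixed gene list in 3 comparisons, per lineage; points are medians and bars are 95% order-statistic intervals over list members, which are not replicates. The horizontal scales differ between panels; naive pluripotency is lowest and visceral endoderm transport highest in E5.5 over EDG9.5, while under TMM scaling the ribosomal protein median of Reactivated endoderm changed sign, as did other medians between -0.32 and 0.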

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

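The tests of markers in other classes, of doublets, of a mix of cells and of thinned cells with G2 and M phase UMIs were chosen after the result was seen, as was the use of 2 alternatives set in advance (the mitochondrial limit and the total) as tests of that pattern, and none of the differences between lineages below was itself tested. G2 and M phase genes differed in direction between lineages in EDG9.5 over EDG7.5, with a median log2 ratio of -0.63 in endoderm (28 of 28 genes lower), -0.22 in epiblast (23 of 28 lower) and 0.34 in trophoblast (28 of 28 higher). With ribosomal protein and mitochondrially encoded genes left out of the total, the medians were -0.63 (-0.83 to -0.50) in endoderm and 0.41 (0.28 to 0.63) in trophoblast, and with cells under 10% mitochondrial share alone they were -0.96 (-1.09 to -0.74) and 0.59 (0.42 to 0.92), which argues against the make-up of the total and cells of high mitochondrial share as the whole cause. The 10% limit left 312 of 581 endoderm and 300 of 588 trophoblast cells in EDG7.5. Other alternatives gave a smaller trophoblast median, below its main interval. It was 0.19 with cells thinned to 1000 UMIs and 0.13 with 50 CPM added, where the endoderm median was -0.39. Epiblast or endoderm cells or RNA in the trophoblast class would need a share of 11.6%. Of their abundant markers, 16 of 22 had upper limits below that, the third lowest at 0.342% (Srgn). Trophoblast cells or RNA in the endoderm class would need 48.8%, and 12 of 12 markers lay below it, the third lowest at 0.605% (Tspan8). These markers come from the lists that named the clusters. Low shares therefore follow in part from the naming and do not by themselves exclude misplaced cells. Of trophoblast cells thinned to 1000 UMIs, 10.7% (8.33 to 13.5) in EDG7.5 and 13.6% (11.5 to 15.9) in EDG9.5 had at least 2 UMIs of these genes, and of endoderm cells 37.2% (33.2 to 41.3) and 30.8% (27.8 to 34.0), intervals that overlap in both lineages. Such overlap does not show that the shares were alike. Stage and library are the same thing here, so a difference between libraries stays open and no biological explanation was tested.

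In EDG9.5, 56 cells left without a name had Gata4, an endoderm gene, at 1031 CPM and Sox2, an epiblast gene, at 389.9 CPM; named endoderm had 819 and 15.0 CPM and named epiblast 5.96 and 1790.5 CPM. Doublets of typical epiblast and endoderm cells would hold at least as many UMIs as single cells, but the median was 1943 UMIs against 4080.5 in epiblast and 3699 in endoderm. Single cells passed from 1000 UMIs, however, so doublets of cells with few UMIs stay open. Free RNA weighing more in cells with few UMIs stays open: the epiblast share of marker UMIs was 12.2% (11.9 to 12.6) in 548 endoderm cells of the same UMI range (median 2926 UMIs) and 38.8% (36.1 to 41.6) in the unnamed cells, but the naming rule itself separates cells by this share, so the test set in advance decides nothing. A mix of ordinary epiblast and endoderm cells stays open too: 20 of the 56 cells lay between the central ranges of these classes, but the ranges come from cells that clustering and naming had already parted from them. No biological explanation was tested.

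S phase genes in EDG9.5 over EDG7.5 had medians of 0.043 in trophoblast (20 of 27 higher), -0.24 in epiblast (26 of 27 lower) and -0.18 in endoderm (21 of 27 lower), and the trophoblast value was -0.0022 with cells thinned to 1000 UMIs. Ribosomal protein genes in Reactivated over EDG9.5 had 0.28 in epiblast (66 of 86 higher) and -0.22 in endoderm (61 of 86 lower), the latter 0.14 under TMM scaling. In E5.5 over EDG9.5 they had 0.24 in epiblast (61 of 88 higher) and -0.50 in endoderm (69 of 87 lower).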

How the results depend on the processing

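Every alternative was chosen in advance except trophoblast without the 3 clusters led by genes of other lists, which was chosen after the values were seen; the cause of each difference below was not tested. Of 96 lineage shares under alternatives, 83 lay within the main value's interval; of 690 medians of the main lists 661 did, and 683 kept their sign; of 2930 other medians 2876 did, and 81 changed sign; of 5498 gene ratios 4364 did, and 5408 kept their sign. The limit of 500 UMIs and 250 genes moved no value, so it says nothing about stability. No leave-one-out or paired analysis was possible because each stage has 1 library.

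With cells under 10% mitochondrial share, epiblast, endoderm and trophoblast made up 42.3%, 29.4% and 28.3% in EDG7.5, epiblast 30.7% and trophoblast 31.7% in EDG9.5; in EDG9.5 over EDG7.5 G2 and M phase had -0.96 in endoderm and 0.59 in trophoblast, and Ctsl in endoderm was reversed at 0.0032. Without the 3 clusters, endoderm and trophoblast made up 37.6% and 30.8% in EDG7.5, 38.2% and 36.1% in EDG9.5, and 33.9% and 36.2% in E5.5 (epiblast 29.9%), and trophoblast G2 and M phase had 0.63 in EDG9.5 over EDG7.5. With doublets kept, E5.5 endoderm made up 33.3%.

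With cells thinned to 1000 UMIs, in EDG9.5 over EDG7.5, cholesterol synthesis was reversed in epiblast (0.025), glycolysis in endoderm (-0.11) and S phase in trophoblast (-0.0022; -0.011 as a mean over cells); naive pluripotency had 0.21 and trophoblast G2 and M phase 0.19. Genes reversed by thinning were Hadh (0.091) and Insig1 (0.21) in that epiblast, Lgals3 (0.0037) and Lgr5 (-0.27) in Reactivated over EDG9.5 trophoblast, and Col4a1 (0.022, endoderm) and Echs1 (0.20, epiblast) in E5.5 over EDG9.5.

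With TMM factors, in Reactivated over EDG9.5, epiblast G2 and M phase had 1.5 and epiblast ribosome biogenesis 1.14; in endoderm ribosome biogenesis had 0.42, autophagy and lysosome -0.032, and ribosomal proteins were reversed at 0.14. Genes reversed were Cd63 (0.13) and Rps12 (0.16) in endoderm, and Echs1 (0.10) and Hsp90aa1 (0.38) in epiblast. In E5.5 over EDG9.5 endoderm, ribosome biogenesis had 0.59 and autophagy and lysosome 0.13, and Amotl2 (0.030), Col4a1 (0.20), Insig1 (0.26) and Sparc (0.10) were reversed, as was Echs1 in epiblast (0.21). Without ribosomal protein and mitochondrially encoded genes in the total, mt-Cytb in endoderm of Reactivated over EDG9.5 was reversed at -0.038.

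With 1 CPM added, trophoblast G2 and M phase had 0.60, 2.48 and 3.42 in EDG9.5 over EDG7.5, Reactivated over EDG9.5 and E5.5 over EDG9.5; glycolysis in trophoblast had 0.46 in the first, and in the last ribosome biogenesis in trophoblast had 1.81 and naive pluripotency -5.39. With 50 CPM added, G2 and M phase had -0.39 in endoderm and 0.13 in trophoblast in the first, 0.90 and 0.95 in the second, and 0.91 and 1.62 in the last. Ribosome biogenesis had -0.10 in endoderm in the first, and 0.83 and 1.19 in trophoblast in the second and last; autophagy and lysosome had -0.64 in epiblast in the second, and naive pluripotency -2.21 in the last.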

Other observations

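The gene groups in this paragraph and the next were chosen after their values were seen, and CPM are given for EDG7.5, EDG9.5, Reactivated and E5.5. In epiblast, the de novo methyltransferase Dnmt3a had 64.3, 64.0, 277 and 519 and its cofactor Dnmt3l 849, 802, 1617 and 244, so that Dnmt3l was highest in Reactivated. Tet1 and Tet2, which oxidise methylcytosine, had 547, 685, 128 and 170.2 and 102, 106, 15.6 and 2.37, and Tet3 28.7, 31.4, 5.46 and 19.7. The maintenance genes Dnmt1 and Uhrf1 had 119, 99, 139 and 162 and 215, 139, 265 and 307. Pou5f1, a pluripotency factor with pseudogene copies, had 56.6, 49.3, 98.7 and 146, less than Sox2 (1364, 1791, 533 and 116) in each library but E5.5; the reason was not tested. The noncoding RNA Xist, of X chromosome silencing, had 8.74, 17.9, 3.51 and 112 in epiblast, 486, 773, 51.4 and 98.8 in endoderm and 164, 254, 46.7 and 49.8 in trophoblast. Each library pooled embryos whose sexes were not examined, so these levels also depend on the mix of sexes. Xist was among the top genes of E5.5 epiblast cluster 8 (568 cells).

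Some imprinted genes had higher CPM in E5.5 than in EDG9.5 and others lower. H19 had 25.5, 75.2, 377 and 6232 in endoderm and 5424, 5398, 4185 and 9535 in trophoblast, Cdkn1c 3.34, 6.23, 16.1 and 195 and Peg10 19.4, 16.0, 81.4 and 211 in trophoblast, and Meg3 167, 196, 137 and 334 in epiblast, while Igf2r and Peg10 had 317, 295, 29.3 and 41.8 and 43.7, 75.9, 136 and 10.8 there. The metallothioneins Mt1 and Mt2, which bind zinc and copper, had 12791, 10465, 3351 and 1159 and 16219, 12007, 5210.4 and 2314 in trophoblast, but Mt1 had 721, 830.5, 2484 and 2240.2 in endoderm. Laptm5 and Pecam1, on the immune and endothelium lists, had 230.4, 219, 54.6 and 1.90 and 226, 201, 28.1 and 4.32 in epiblast, and Msx1, on the uterine epithelium list, 303, 257, 149.7 and 10.3 in trophoblast.

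Glycolysis genes were higher in Reactivated than EDG9.5 in all 3 lineages, and sets of hypoxia-inducible genes and of MYC targets were examined beside them, the latter a test chosen after the result was seen. The hypoxia set, without glycolysis genes, had medians of 0.32 (-0.43 to 1.56) in epiblast (10 of 16 higher), 0.24 (-0.28 to 0.61) in endoderm (12 of 18) and -0.080 (-2.18 to 1.52) in trophoblast (7 of 14). It was set in advance that an interval reaching 0 would count against hypoxia, but members went both ways, so such a median decides nothing. Mif and Fam162a were higher and Vegfa and Egln1 lower in all 3 lineages. Ankrd37, Ero1l, Higd1a and Adm were also higher and Kdm3a and Mxi1 lower in all 3, with some differences small or near the floor. In EDG9.5 and Reactivated, Adm had 3.11 and 3.52 CPM in trophoblast and Mxi1 40.1 and 36.7 CPM in epiblast. Ribosome biogenesis and MYC targets had 0.80 (0.36 to 0.99), 0.089 (-0.25 to 0.39) and 1.06 (0.91 to 1.30), also with members both ways in endoderm, so a common MYC response stays open too. Under the alternatives of scaling, thinning, mitochondrial limit and doublets, the glycolysis medians stayed within their main intervals, the lowest being 1.68 in epiblast, 0.80 in endoderm and 1.33 in trophoblast; hypoxia and MYC stay open, as does a difference between libraries.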
